A study of Mus musculus with 12 samples.

How the data were processed

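Hippocampi of 12 wild-type mice, 3 per sex and extinction level, were dissected and frozen, total RNA was enriched for polyadenylated RNA, and libraries were made with an mRNA kit from 1 µg of total RNA, per the labels' protocols. The submitters' processing notes name TopHat2, Bowtie2, HTSeq, StringTie 1.3.3b and DESeq2 and the builds GRCm38.p5 and mm10, without saying which tool made which file. Whether counting used the strand is not given in the sources used here. The authors deposited a table of TPM for each sex, with 52636 genes and a column per mouse. TPM divides by transcript length and by the library's total, so a transcript that takes a large share of a library lowers all others, and it keeps no record of depth. The authors also deposited, per the file headers, a DESeq2 table for each sex with the mean of normalized counts, the log2 fold change, its standard error, the test statistic (a score, the fold change over its standard error), the p-value and the adjusted p-value. The deposited tables do not name the direction of the log2 fold change. It had a correlation across genes of -0.58 in males and -0.46 in females with the TPM change from high to low extinction, and 101 of 101 called genes in males and 133 of 134 in females had the opposite sign to their TPM change. The authors' fold changes were therefore multiplied by -1 to read low minus high extinction. The 2 sexes' tables were made separately, so differences were taken within each sex and then averaged or subtracted.

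Library columns were matched to mice by the mouse names in the labels, and replicate numbers follow the order of the records and pair no mice. No 2 libraries were identical, and correlations of log2(TPM + 1) between libraries ran from 0.973 to 0.983. Counts per library were not analysed here, so no count model was run, and depth per library is unknown. Tests were run on log2(TPM + 1), which understates changes of low genes. Genes with a mean of at least 1 TPM were tested with limma 3.58.1 in R 4.3.3 with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, within each sex over its 6 libraries, and over all 12 libraries for the average and the interaction. The interaction is the male change minus the female change. Of 42 gene lists fixed before the data were examined, 1 of sex chromosome genes served to check labels and 41 were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Tia1 was tested with an exact permutation of labels within sex. The rule for named genes took Tia1, up to 10 genes per direction called by limma with no overlap between low and high libraries, filled up by smallest p and then described as not passing, the 10 smallest adjusted p per direction in each of the authors' tables at a mean of at least 1 TPM, 5 per direction for the interaction, and members of the lists. Genes called in both of the authors' tables and genes of a chromosome 7 locus were named after their values were seen.

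Alternatives fixed before the data were examined were other pseudocounts, filters, scalings, variance models, a joint fit, a list correlation estimated per list, fry, and leaving out each replicate. Estimating the list correlation also makes the test rest on the few libraries instead of on all genes, so it has little power. Added after the data were seen were leaving out ribosomal RNA-derived genes, combining the authors' fold changes, camera on the authors' statistics and an exact permutation of list means. The limma step was tested on simulated data with known changes in 50 genes per size. At a log2 change of 1.0 it called 70% of them in males, 76% in females, 92% on average and 72% for the interaction, and at 0.5 it called 16%, 32%, 66% and 14%. False calls numbered 8, 7, 11 and 7. Changes of 0.5, 1, 2 and 3 were planted together, which loosens the adjusted threshold. The shares can therefore be lower where few genes change. Gene positions are from GENCODE M21 on GRCm38, in which 52489 of 52636 gene identifiers were found and 49121 with the same version. Correlations, permutations and figures used Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.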

Results

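RNA was sequenced from the hippocampus, a brain region needed for contextual memory, of 12 wild-type C57BL6/J mice aged 18 weeks. The mice formed 4 groups of 3: males with high extinction, males with low extinction, females with high extinction and females with low extinction. Fear extinction is the decline of a learned fear response when the feared cue or place is met again without harm. Each library came from a different mouse, so the spread between libraries includes the spread between animals. The comparisons asked which transcripts differed between low and high extinction in males, in females and on average over both sexes, and which differed in another way in the 2 sexes. All changes below are low minus high extinction. Levels per library are the deposited TPM, transcript abundances corrected for length and scaled to the same total in each library. Fold changes called the authors' come from their deposited DESeq2 table for each sex, turned to the same direction. The number of reads per library is unknown, and the mean normalized counts in the authors' tables summed to 42.6 M in males and 43.4 M in females. Between 18170 and 19062 genes reached 1 TPM in a library. Transcripts derived from ribosomal RNA took from 7.04% of all TPM, in replicate 3 of the low-extinction females, to 23.5%, in replicate 1 of the high-extinction males. Xist, expressed from the inactive X chromosome, lay at 179.95 TPM or more in each female library and at 0.822 TPM or less in each male library.

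Tia1, named in the title of the series, encodes an RNA-binding protein of stress granules that also regulates splicing and translation. Its gene (ENSMUSG00000071337.11) spans positions 86404219 to 86433405 on the plus strand of chromosome 6 in GRCm38 and overlaps the annotated gene Gm44790 on the same strand. Tia1 was higher at low extinction in both sexes. In males it lay at 88.6 ± 17.6 TPM at low and 69.3 ± 20.9 TPM at high extinction (SD, n = 3 each). In females it lay at 96.2 ± 19.3 and 77.0 ± 3.25 TPM (SD, n = 3 each). In the authors' deposited tables Tia1 was 1.21-fold higher in males (log2 SE 0.07, DESeq2 adjusted p = 0.0441) and 1.18-fold higher in females (log2 SE 0.06, DESeq2 adjusted p = 0.0363). On log2(TPM + 1) the change was 0.37 in males and 0.30 in females, each with a two-sided exact permutation p of 0.2, where 3 libraries against 3 cannot go below 0.1. Averaged over the sexes it was 0.34 (two-sided exact permutation p = 0.065 over 400 assignments), and the limma adjusted p was 0.632. Leaving out single libraries gave changes from 0.19 to 0.60 in males, 0.15 to 0.43 in females and 0.24 to 0.45 on average. The exact p on average was 0.03 without replicate 3 of the high-extinction males, 0.045 without replicate 1 of the low-extinction males and 0.04 without replicate 1 of the low-extinction females, and over 0.05 without any other single library. The male and female log2 changes of Tia1 in the authors' deposited tables differed by 0.04 (SE 0.10), and a difference between the sexes was not detected.

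**Figure D1:**
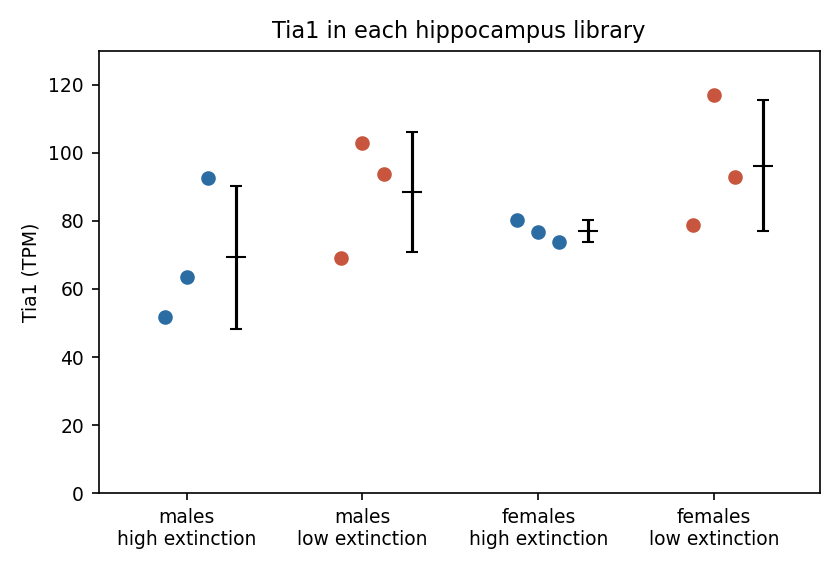
Tia1 level in TPM (vertical axis) in each of the 12 libraries, by sex and extinction level. Points are single mice, and the bar beside each group is the mean with its SD over 3 mice; the groups overlap within each sex, with means of 88.6 against 69.3 TPM in males and 96.2 against 77.0 TPM in females.

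In males, the authors' deposited table called Cd74 and the cilia genes Foxj1, Tekt1 and Ccdc153 higher at high extinction, and Hif3a and the nuclear RNAs Miat and Snhg11 higher at low extinction. The authors' deposited table called 101 genes, 78 higher at high and 23 higher at low extinction, and 70 of them differed by less than 2-fold. Cd74, the invariant chain of MHC class II, was 3.87-fold higher at high extinction in the authors' deposited table (log2 SE 0.30, DESeq2 adjusted p = 5.36e-07). Cd74 lay at 7.77 ± 1.81 TPM at high and 1.82 ± 0.851 TPM at low extinction (SD, n = 3 each). Foxj1, the master regulator of motile cilia on chromosome 11 from 116330704 to 116335399, was 1.95-fold higher (DESeq2 adjusted p = 0.00019), Tekt1 2.81-fold (DESeq2 adjusted p = 0.000249) and Ccdc153 2.98-fold higher (DESeq2 adjusted p = 0.000275) in the authors' deposited table. In the same deposited table of the authors, Crb2 was 1.86-fold, Slc5a3, a myo-inositol transporter, 1.52-fold, Fam46a 1.71-fold, Banp 1.42-fold and the cyclin gene Ccnd2 1.29-fold higher at high extinction. Slc5a3 overlaps Mrps6 on the same strand. Toward low extinction, the authors' deposited table gave Hif3a, a hypoxia-inducible factor, a 2.02-fold difference (log2 SE 0.15, DESeq2 adjusted p = 5.36e-07). Hif3a lay at 6.78 ± 1.19 TPM at low and 2.63 ± 0.531 TPM at high extinction (SD, n = 3 each). The authors' deposited table also gave Xdh, xanthine dehydrogenase, a 1.75-fold, Etnppl, an astrocyte enzyme, a 1.59-fold, Mirt1 a 1.84-fold, Gm37607 a 1.89-fold and Ndst3 a 1.29-fold difference in that direction. The nuclear RNAs Miat, Snhg11 and Malat1 were 1.23-fold, 1.21-fold and 1.25-fold higher at low extinction in the authors' deposited table.

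Among the gene lists fixed before the data were examined, 9 of 41 passed in males with camera on log2(TPM + 1), 6 toward high and 3 toward low extinction. Choroid plexus markers (20 genes) had a median log2 change of -1.68 (camera adjusted p = 7.01e-14, and adjusted p = 0.696 with an estimated correlation). The authors' deposited table called 0 of them over all genes and 0 adjusted over the list alone. Ttr, the main choroid plexus transcript, lay at 2874, 3300 and 299 TPM in the high-extinction and at 906, 41.3 and 49.6 TPM in the low-extinction males. Ependymal markers had a median of -0.87 (13 genes, camera adjusted p = 2.75e-13, and adjusted p = 0.677 with an estimated correlation). The authors' deposited table called 6 of them, and 10 when adjusted over the list alone. Meningeal fibroblast markers had a median of -0.68 (14 genes, camera adjusted p = 9.6e-11, and adjusted p = 0.677 with an estimated correlation), with 1 called in the authors' deposited table and 9 adjusted over the list alone. Interferon and antigen presentation genes had a median of -0.27 (25 genes, camera adjusted p = 2.75e-07, and adjusted p = 0.677 with an estimated correlation). The authors' deposited table called 3 of them, among them H2-Ab1, which was 4.53-fold higher, and H2-Eb1, which was 3.12-fold higher at high extinction, both MHC class II genes, and 8 adjusted over the list alone. Immediate early genes, which neuronal activity induces, had a median of -0.23 (30 genes, camera adjusted p = 1.27e-06, and adjusted p = 0.696 with an estimated correlation). The authors' deposited table called 2, Egr2 at 2.07-fold and Junb at 1.31-fold higher at high extinction, and 8 adjusted over the list alone. The mean of the immediate early genes per library, minus the mean over 12 libraries, lay at -0.30, 0.07 and -0.27 at high extinction. At low extinction it lay at -0.34, -0.48 and -0.40, so replicate 2 of high extinction carried much of the difference. Heat shock and unfolded protein response genes had a median of -0.09 (26 genes, camera adjusted p = 0.020, and adjusted p = 0.970 with an estimated correlation), with 2 called in the authors' deposited table and 3 adjusted over the list alone. Toward low extinction passed the nuclear-retained and small RNA host transcripts (15 genes, median 0.14, camera adjusted p = 0.000318, and adjusted p = 0.677 with an estimated correlation), of which the authors' deposited table called 4, and 7 adjusted over the list alone. Their mean per library, minus the mean over 12 libraries, lay at -0.23, -0.07 and -0.09 at high and at -0.11, -0.01 and 0.04 at low extinction. The 2 groups of males overlapped, and the lowest value, -0.23, came from 1 library. Glucocorticoid-induced genes (20 genes, median 0.11, camera adjusted p = 0.00251, and adjusted p = 0.896 with an estimated correlation) and the 15 mitochondrially encoded genes (median 0.13, camera adjusted p = 0.00597, and adjusted p = 0.970 with an estimated correlation) passed in the same direction. The authors' deposited table called 1 glucocorticoid-induced gene, Hif3a, and 3 adjusted over the list alone, and 0 mitochondrially encoded genes either way. The other 32 lists did not pass in males, among them the 30 stress granule and TIA1-family genes (median -0.02, camera adjusted p = 0.959). On log2(TPM + 1) limma called 0 of 18303 genes in males, with 1151 at an unadjusted p under 0.05, and leaving out any single library gave 2 to 6 genes. Single left-out libraries ended the call of heat shock genes, without replicate 2 or 3 of high or 3 of low extinction (camera adjusted p 0.070 to 0.328). They also ended those of glucocorticoid-induced genes, without replicate 3 of either group (0.0703 and 0.122), and of mitochondrially encoded genes, without replicate 1 of high extinction (0.168).

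In females, the authors' deposited table called the immediate early genes Egr4, Egr1 and Fosb higher at high extinction, and Col3a1, Myh11, Prkcd and the nuclear RNAs Meg3 and Snhg11 higher at low extinction. The authors' deposited table called 134 genes, 45 higher at high and 89 higher at low extinction, and 123 of them differed by less than 2-fold. Toward high extinction, the authors' deposited table gave the activity-induced transcription factor genes Egr4 a 1.49-fold (log2 SE 0.10, DESeq2 adjusted p = 2.03e-05), Egr1 a 1.27-fold, Fosl2 a 1.27-fold, Fosb a 1.35-fold and Nr4a3 a 1.22-fold difference. Egr4 lay at 39.4 ± 2.63 TPM at high and 28.1 ± 4.81 TPM at low extinction (SD, n = 3 each). Sst, the neuropeptide of a class of interneurons, was 1.26-fold, Kcng1, a potassium channel subunit, 1.33-fold, Cbfa2t3 1.26-fold and Cox8a, a subunit of cytochrome c oxidase, 1.24-fold higher at high extinction in the authors' deposited table. Toward low extinction, the authors' deposited table gave Col3a1, a fibrillar collagen on chromosome 1 from 45311538 to 45349706, a 2.38-fold difference (log2 SE 0.20, DESeq2 adjusted p = 2.05e-06). Col3a1 lay at 2.16 ± 0.401 TPM at low and 0.946 ± 0.152 TPM at high extinction (SD, n = 3 each). In the same direction the authors' deposited table gave Slc6a13 a 2.03-fold, Col6a3 a 1.98-fold, Igf2 a 1.39-fold and the smooth muscle myosin gene Myh11 a 1.90-fold difference. Igf2 lay at 22.9 ± 1.68 TPM at low and 24.6 ± 4.75 TPM at high extinction (SD, n = 3 each), so its TPM did not follow the count-based fold. Prkcd, a protein kinase C gene abundant in the thalamus, was 1.59-fold higher (log2 SE 0.10, DESeq2 adjusted p = 3.16e-08), Zic4 1.84-fold, Cacng5 1.52-fold and the zinc finger gene Zkscan2 1.37-fold higher at low extinction in the authors' deposited table. Zic4 overlaps Zic1 on the opposite strand.

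Of the 41 lists, 10 passed in females, 5 in each direction. Immediate early genes had a median log2 change of -0.16 on log2(TPM + 1) (30 genes, camera adjusted p = 6.18e-12, and adjusted p = 0.636 with an estimated correlation). The authors' deposited table called 10 of them, all higher at high extinction and among them Arc at 1.28-fold and Egr3 at 1.17-fold, and 20 adjusted over the list alone. The mean of the immediate early genes per library, minus the mean over 12 libraries, lay at 0.44, 0.39 and 0.25 at high extinction. At low extinction it lay at 0.20, 0.14 and 0.30, so the 2 groups of females overlapped (two-sided exact permutation p = 0.2). Heat shock and unfolded protein response genes (26 genes, median -0.03, camera adjusted p = 0.000119, and adjusted p = 0.636 with an estimated correlation) lay toward high extinction. Oxidative phosphorylation genes (62 genes, median -0.01, camera adjusted p = 0.000732, and adjusted p = 0.893 with an estimated correlation) and blood cell markers (7 genes, median -0.25, camera adjusted p = 0.0385, and adjusted p = 0.893 with an estimated correlation) also lay toward high extinction. Oxidative phosphorylation genes had a median of -0.095 in the authors' deposited table. There 4 of 62 were higher at low extinction, against 27 of 62 on TPM. The authors' deposited table called 3 heat shock genes, 1 oxidative phosphorylation gene and 0 blood cell markers, and 8, 9 and 0 adjusted over the list alone, with 1 of the 9 higher at low extinction. The 54 cytosolic ribosomal protein genes passed toward high extinction too (camera adjusted p = 0.00159, and adjusted p = 0.636 with an estimated correlation). Their median was -0.02 and their mean 0.04, beside a median of 0.06 over all tested genes. The authors' deposited table called 1 of them, and 1 adjusted over the list alone. Toward low extinction, meningeal fibroblast markers had a median of 0.64 (15 genes, camera adjusted p = 3.21e-07, and adjusted p = 0.637 with an estimated correlation), with 5 called in the authors' deposited table and 10 adjusted over the list alone. Thalamus and habenula markers had a median of 0.28 (16 genes, camera adjusted p = 0.000537, and adjusted p = 0.503 with an estimated correlation), with 3 called in the authors' deposited table and 5 adjusted over the list alone. Nuclear-retained and small RNA host transcripts had a median of 0.25 (15 genes, camera adjusted p = 0.00246, and adjusted p = 0.642 with an estimated correlation), with 2 called, Meg3 and Snhg11, and 6 adjusted over the list alone in the authors' deposited table. Endothelial and pericyte markers (22 genes, median 0.21, camera adjusted p = 0.0109, and adjusted p = 0.893 with an estimated correlation) and splicing factor genes (35 genes, median 0.15, camera adjusted p = 0.0291, and adjusted p = 0.893 with an estimated correlation) completed this direction. Splicing factor genes had a median of 0.03 in the authors' deposited table, and all tested genes had a median of 0.06 on log2(TPM + 1). The authors' deposited table called 2 endothelial and pericyte markers, among them Acta2 at 1.79-fold, and 3 adjusted over the list alone, and 1 splicing factor gene, Srsf5 at 1.16-fold, and 6 adjusted over the list alone. The other 31 lists did not pass, among them the stress granule genes (median 0.09, camera adjusted p = 0.170). On log2(TPM + 1) limma called 2 of 18668 genes, Fam103a1 (2.66, limma adjusted p = 0.00103) and Bzw1 (-1.63, limma adjusted p = 0.0126), with 1648 at an unadjusted p under 0.05. Leaving out single libraries gave 4 to 10 genes, and Bzw1 missed the threshold without replicate 1 of low extinction (limma adjusted p = 0.0542). The authors' deposited table gave these genes log2 changes of -0.01 and 0.04 in females. Single left-out libraries ended the calls of blood cell markers, without replicate 2 of high or 1 or 2 of low extinction (camera adjusted p 0.153 to 0.200), and of endothelial and pericyte markers, without replicate 3 of high or 1 of low extinction (0.0908 and 0.105). They also ended those of splicing factor genes, without replicate 3 of either group (0.230 and 0.0996), and of nuclear-retained transcripts, without replicate 2 of low extinction (0.065).

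**Figure D2:**
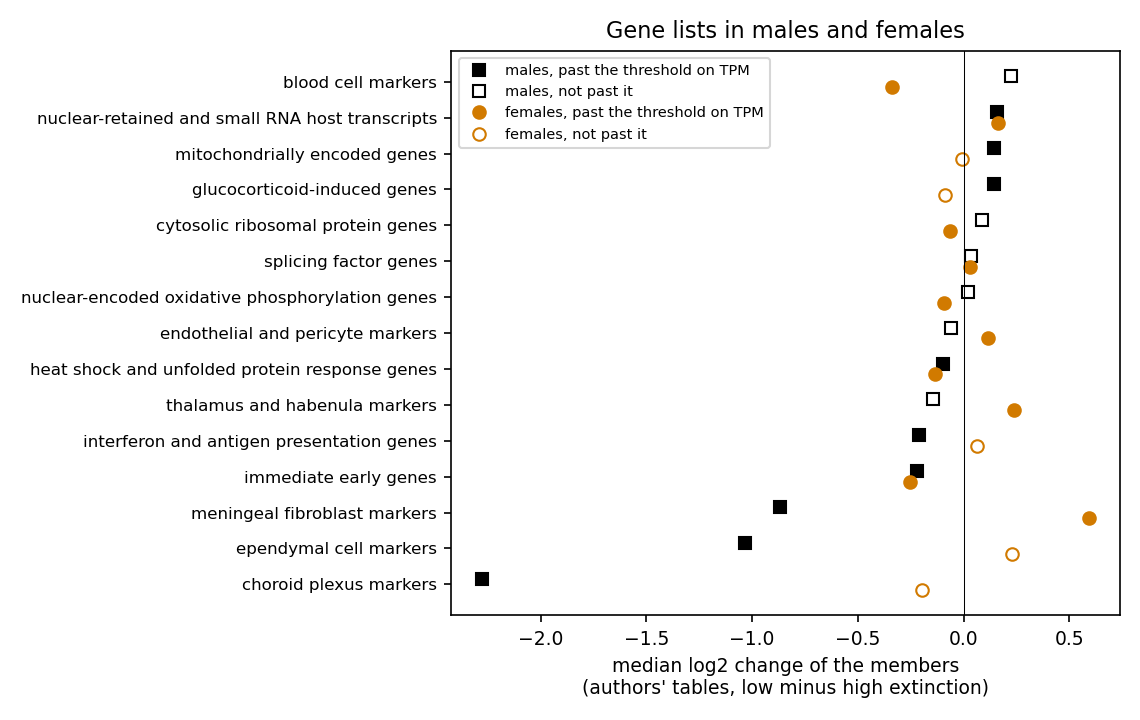
Median log2 change of each gene list's members in the authors' deposited tables (horizontal axis, low minus high extinction) in males (squares) and females (circles), for the lists that passed in at least 1 sex with camera on log2(TPM + 1). Filled symbols passed in that sex; meningeal fibroblast markers lay at -0.87 in males and 0.60 in females, and immediate early genes at -0.22 and -0.25.

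In both sexes, the authors' deposited tables called Tia1, Zkscan2 and the nuclear RNAs Meg3 and Snhg11 higher at low extinction, and Junb and Dnajb1 higher at high extinction. The authors' deposited tables shared 13 called genes, of which 9 had the same direction. Tia1, Meg3, Snhg11, Zkscan2, Gm21781, A230103L15Rik and 9330162G02Rik were higher at low extinction in both deposited tables of the authors, 7 genes where independent lists would share 0.131 (23 male and 89 female calls among 15642 genes with an adjusted p in both). A Fisher exact test of this overlap gave p = 3.46e-11, but it takes genes as independent. Genes that move together from mouse to mouse are not, so this p does not measure the spread between mice. Meg3, an imprinted long non-coding RNA on chromosome 12, was 1.19-fold higher in males and 1.23-fold in females in the authors' deposited tables, and Snhg11 was 1.21-fold and 1.24-fold higher. Zkscan2 was 1.27-fold higher in males (DESeq2 adjusted p = 0.00984) and 1.37-fold in females (DESeq2 adjusted p = 1.52e-07). A230103L15Rik lies within Snhg14, and 9330162G02Rik lies opposite Ube3a, and whether the counts separated these pairs is not given in the sources used here. Junb and the heat shock co-chaperone gene Dnajb1 were higher at high extinction in both, 2 genes against 0.201 for independent lists (70 of the 78 male calls and all 45 female calls had an adjusted p in both). The Fisher exact p was 0.0173, with the same limit. Dnajb1 was 1.31-fold higher in males and 1.22-fold in females, and Junb had log2 changes of -0.39 and -0.38, in the authors' deposited tables. Combining the authors' deposited fold changes by inverse variance, chosen after the data were seen, 194 of 18043 genes differed on average, 109 higher at low and 85 higher at high extinction. This average leans to the sex with the smaller standard error, while the limma average weights both sexes equally. Of the 194, 179 had the same sign in both sexes. These calls were not set against other splits of the mice. On log2(TPM + 1) limma called 0 of 18499 genes on average, with 1424 at an unadjusted p under 0.05.

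Of the 41 lists, 9 passed on average over the sexes. Immediate early genes had a median of -0.18 (30 genes, camera adjusted p = 1.29e-14, and adjusted p = 0.302 with an estimated correlation), with 0 called over all genes and 8 adjusted over the list alone on TPM, and 14 and 21 in the combined fold changes. The mean of the list per library differed by -0.19 (two-sided exact permutation p = 0.015, adjusted p = 0.307 over the lists). Nuclear-retained and small RNA host transcripts had a median of 0.15 (15 genes, camera adjusted p = 1.13e-05, and adjusted p = 0.302 with an estimated correlation), with 0 called over all genes and 7 adjusted over the list alone on TPM, and 6 and 8 in the combined fold changes. The remaining lists toward high extinction were choroid plexus (median -0.87), ependymal (median -0.38), heat shock (median -0.04), interferon (median -0.06) and oligodendrocyte markers (median -0.06), with camera adjusted p from 1.12e-09 to 0.0293. Mitochondrially encoded genes (median 0.10, camera adjusted p = 0.0125) and splicing factor genes (median 0.05, camera adjusted p = 0.0287) lay toward low extinction. These 7 lists each had an adjusted p = 0.928 with an estimated correlation. In the combined fold changes 6 heat shock, 2 ependymal and 2 splicing factor genes were called, and 10, 4 and 8 adjusted over the list alone. They called 0 choroid plexus, 0 interferon, 2 oligodendrocyte and 0 mitochondrially encoded genes, and 1, 0, 2 and 0 adjusted over the list alone. The 2 oligodendrocyte genes went 1 in each direction, and the choroid plexus gene was higher at low extinction, against its list. With camera on the authors' statistics, chosen after the data were seen, the interferon (adjusted p = 0.159) and mitochondrially encoded genes (adjusted p = 0.0904) did not pass on average. Only there passed meningeal (1.03e-05) and thalamus and habenula markers (0.000163), toward low extinction. So did oxidative phosphorylation (0.000966), circadian (0.0118), neurotrophin and MAPK/CREB (0.0281) and monoamine and acetylcholine receptor genes (0.0465), toward high extinction. On log2(TPM + 1) the meningeal list lay toward high extinction without passing (camera adjusted p = 0.153). Single left-out libraries ended calls of lists. The oligodendrocyte list was lost without male high replicate 2, male low replicate 1 or 2, female high replicate 1 or 3 or female low replicate 1 or 3 (camera adjusted p 0.0546 to 0.619). Splicing factor genes were lost without male high or male low replicate 1 or 2, or replicate 3 of either female group (0.0589 to 0.157). Mitochondrially encoded genes were lost without male high replicate 1 or replicate 2 of either female group (0.0689 to 0.255), and interferon genes without female high replicate 2 or female low replicate 1 (0.070 and 0.0828). Over all 18046 genes measured in both sexes, the male and female changes on log2(TPM + 1) had a Pearson r of 0.02 across genes, which are not independent replicates, and a Spearman rho of 0.06. Relabelling the libraries within each sex gave a permutation p of 0.644 for r and 0.277 for rho, with r from -0.18 to 0.18.

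**Figure D3:**
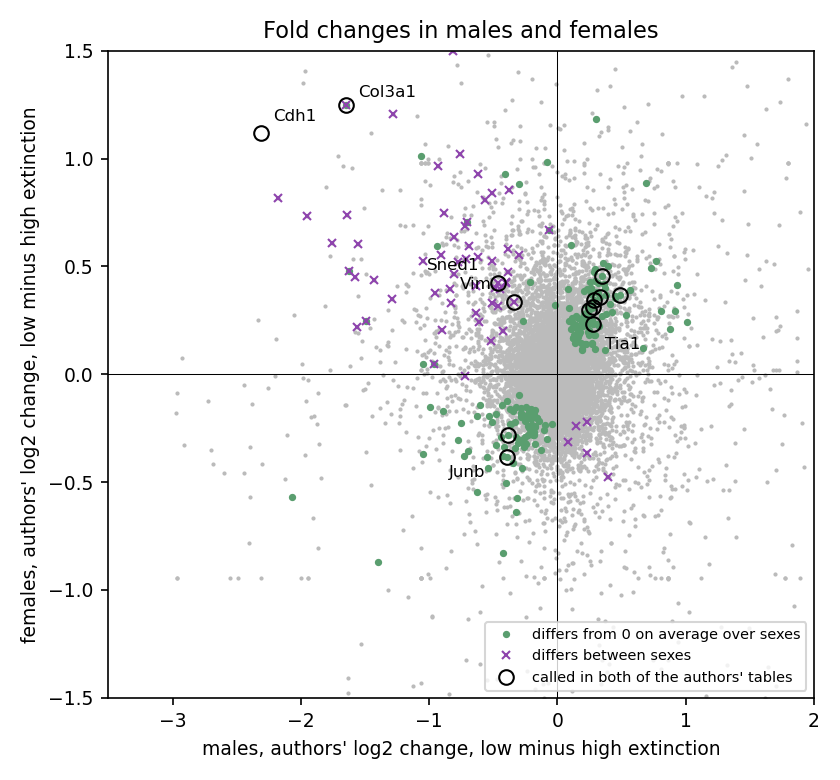
Log2 change, low minus high extinction, in the authors' deposited tables for males (horizontal axis) and females (vertical axis), with each point a gene with a mean of at least 1 TPM; 216 genes lie outside the axes. Green points are the 194 genes that differed from 0 on average over the sexes, purple crosses the 60 genes that differed between the sexes, and open circles the 13 genes called in both tables.

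The change from high to low extinction was lower in males than in females for Col3a1, Cd74, Foxj1 and Prkcd, by the difference of the authors' deposited fold changes. Col3a1, Vim, Sned1 and Cdh1, an epithelial cadherin gene, were called in opposite directions in the authors' deposited tables, higher at high extinction in males and at low extinction in females. Independent lists would share 0.398 genes where these shared 4 (70 male and 89 female calls among 15642 genes). A Fisher exact test gave p = 0.000674, but it takes genes as independent and does not measure the spread between mice. Col3a1 was 3.14-fold higher at high extinction in males and 2.38-fold higher at low extinction in females in the authors' deposited tables, and Vim, an intermediate filament gene, was 1.26-fold in each direction. Taking the difference of the authors' 2 fold changes, chosen after the data were seen, 60 genes differed between the sexes, 55 with a lower change in males. The 60 calls were not set against other splits of the mice. On log2(TPM + 1) limma called 1 of 18499 genes for the interaction, Zfp605 (-1.21, limma adjusted p = 0.0071), with 1466 at an unadjusted p under 0.05. Of the 41 lists, 12 passed for the interaction. Meningeal fibroblast markers had a median difference, male minus female, of -1.34 (camera adjusted p = 1.11e-15, and adjusted p = 0.278 with an estimated correlation), ependymal markers of -1.01 (camera adjusted p = 9.16e-07, and adjusted p = 0.820 with an estimated correlation) and thalamus and habenula markers of -0.38 (camera adjusted p = 0.000957, and adjusted p = 0.154 with an estimated correlation). The combined fold changes called 6, 4 and 1 genes of these 3 lists, and 14, 5 and 3 adjusted over the list alone. Choroid plexus markers had the same direction (median -1.90, camera adjusted p = 7.09e-05, and adjusted p = 0.902 with an estimated correlation), as had interferon and antigen presentation genes (median -0.29, camera adjusted p = 0.000128, and adjusted p = 0.820 with an estimated correlation). Endothelial and pericyte markers (median -0.20, camera adjusted p = 0.034, and adjusted p = 0.849 with an estimated correlation) and perineuronal net and extracellular matrix genes (median -0.19, camera adjusted p = 0.0397, and adjusted p = 0.820 with an estimated correlation) had the same direction. The combined fold changes called 0, 4, 1 and 2 genes of these 4 lists, and 1, 6, 4 and 5 adjusted over the list alone. In the opposite direction lay oxidative phosphorylation genes (median 0.03, camera adjusted p = 0.000417, and adjusted p = 0.902 with an estimated correlation) and glucocorticoid-induced genes (median 0.12, camera adjusted p = 0.000957, and adjusted p = 0.849 with an estimated correlation). So did mitochondrially encoded genes (median 0.03, camera adjusted p = 0.0254, and adjusted p = 0.902 with an estimated correlation) and postsynaptic density genes (median 0.07, camera adjusted p = 0.0254, and adjusted p = 0.902 with an estimated correlation). Ribosomal protein genes passed in that direction too (camera adjusted p = 0.000492, and adjusted p = 0.849 with an estimated correlation), with a median of 0.06 and a mean of -0.06, beside a median of -0.09 over all tested genes. The combined fold changes called 1, 0, 0, 0 and 0 genes of these 5 lists, and 1, 2, 0, 0 and 1 adjusted over the list alone. Single left-out libraries ended the calls of 7 of the 12 lists. Male high replicate 1 ended those of choroid plexus markers (camera adjusted p = 0.114) and oxidative phosphorylation genes (0.403), and female high replicate 3 that of glucocorticoid-induced genes (0.073). Mitochondrially encoded genes were lost without male high or female high replicate 1 or female low replicate 1 or 3 (0.159 to 0.712). Postsynaptic density genes were lost without male high or male low replicate 2, female high replicate 3 or female low replicate 2 (0.073 to 0.286). Perineuronal net genes were lost without male high replicate 1 or 2, male low replicate 2, female high replicate 2 or 3 or female low replicate 1 (0.0694 to 0.155). Endothelial and pericyte markers were lost without any of these 6 and without male low replicate 3 or female low replicate 2 (0.0627 to 0.183). The meningeal and the thalamic lists also passed with fry (fry adjusted p = 0.0439 and 0.00946). Immediate early genes did not pass (median -0.10, camera adjusted p = 0.859), nor did nuclear-retained and small RNA host transcripts (median -0.10, camera adjusted p = 0.929).

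**Figure D4:**
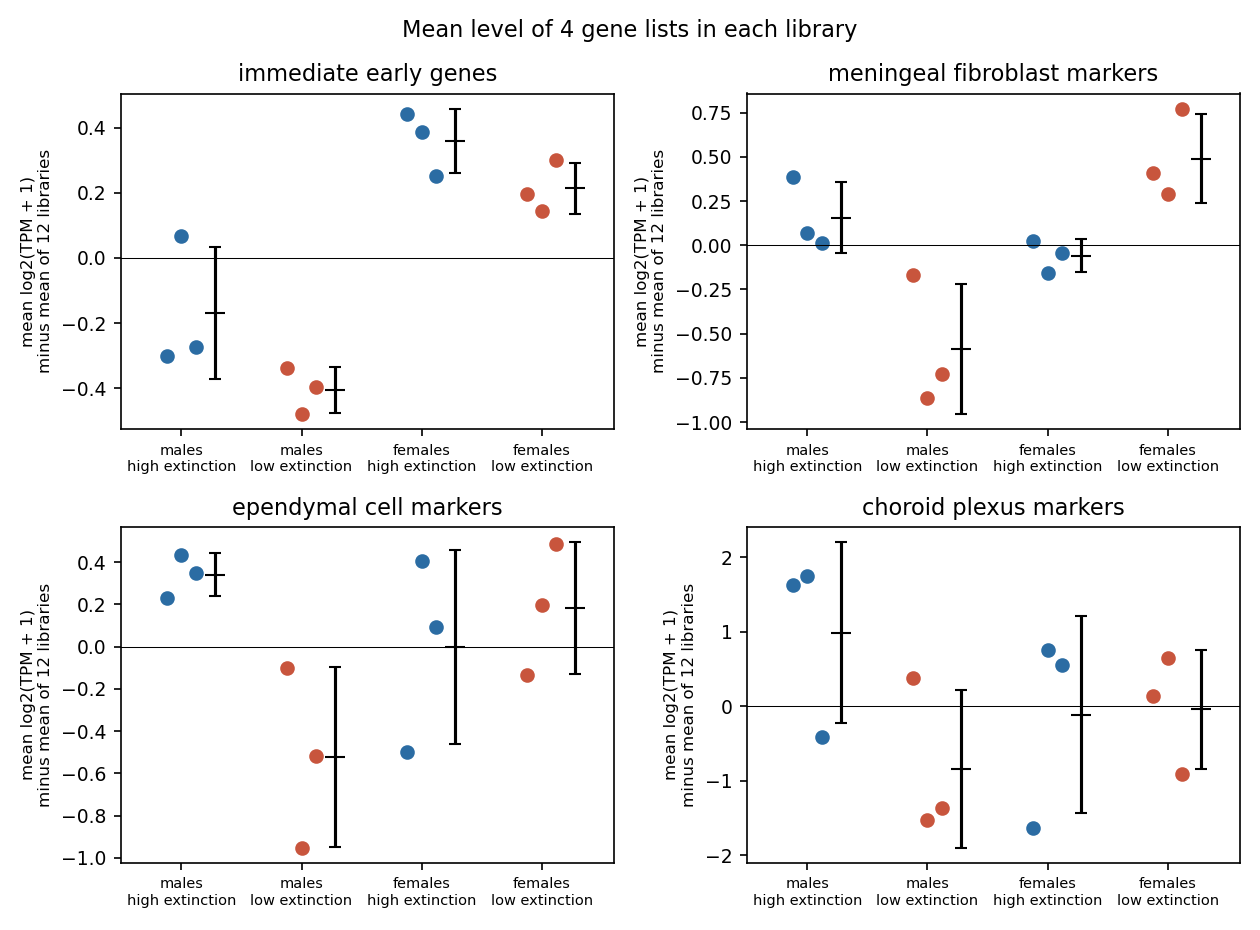
Mean log2(TPM + 1) of the members of 4 gene lists in each library, minus the mean over the 12 libraries (vertical axes), by sex and extinction level. Points are single mice, and bars are the mean and SD over 3 mice; the meningeal list was 0.74 lower at low extinction in males and 0.55 higher in females, and choroid plexus markers ranged from -1.63 to 1.75.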

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

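The tests of lincRNA genes, of GC content and length, of choroid plexus with ependymal markers and of the meningeal list over the median gene were chosen after the results were seen, in place of first tests that could not decide, and the combined fold changes were chosen after the data were seen. Each result here was marked because its change differed between males and females in a test of that difference. Zfp605 had a difference, male minus female, of -1.21 on log2(TPM + 1). From the authors' deposited fold changes, 60 genes differed, with Cd74 at -2.69, Col3a1 at -2.90, Igf2 at -2.10, Ccdc153 at -2.03, Slc6a13 at -1.78, Tekt1 at -1.74, Ccdc187 at -1.46, Foxj1 at -1.01, Sned1 at -0.89, Prkcd at -0.74, Vim at -0.67 and Cox8a at 0.40. For Igf2 the TPM in females did not follow the count-based fold that enters this difference. Median differences of the lists on TPM were -1.90 for choroid plexus, -1.34 for meningeal, -1.01 for ependymal, -0.38 for thalamus and habenula, -0.29 for interferon and antigen presentation, -0.20 for endothelial and pericyte and -0.19 for perineuronal net genes. They were 0.12 for glucocorticoid-induced, 0.0701 for postsynaptic density, 0.0639 for ribosomal protein (with a mean of -0.06), 0.0328 for oxidative phosphorylation and 0.0316 for mitochondrially encoded genes. None of these 12 lists passed with an estimated correlation (adjusted p 0.154 to 0.902), and 2 passed with fry. The estimated setting has little power with few libraries, so its failure decides little. None of the 12 lists passed with the exact permutation of list means (adjusted p = 0.1025 at the lowest). The meningeal and perineuronal net lists had an exact permutation p of 0.005, the smallest that test can give. Their adjusted p was still 0.1025, so the exact test could hardly pass a list and its failure decides little.

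Chance could not be excluded for the genes and lists of the interaction or the lists of the average. For the interaction, 27 of 100 splits gave as many genes as the real 1, with 2 at most in another split, and 7 of 100 gave as many lists as the real 12, with 14 at most. For the average, 34 of 100 gave as many lists as the real 9, with 13 at most. A real count of 0 genes, on average (100 of 100 splits as many, 3 at most) and in males (10 of 10, 5 at most), is met by any split and decides nothing. Within a sex, 3 against 3 make 10 splits, too few for a share under 0.05. Males had 9 lists (4 of 10 splits as many, 15 at most), and females 2 genes (8 of 10, 10 at most) and 10 lists (3 of 10, 12 at most).

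The genes called on TPM were Fam103a1 and Bzw1 in females and Zfp605 for the interaction. All 3 of 3 had a TPM change outside the 95% interval of the authors' count-based change, and 0 of 3 had a count-based unadjusted p under 0.05 in the same direction. Fam103a1 lay at 45.3 to 55.3 TPM in low-extinction and 6.63 to 8.13 TPM in high-extinction females and took both levels within each male group, while its count-based log2 change was -0.01 with an interval from -0.21 to 0.18. This argues against extinction level and is consistent with an error of the TPM estimate.

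With camera at the preset correlation, meningeal markers passed in opposite directions in the sexes, while ependymal and choroid plexus markers passed in males and not in females (camera adjusted p = 0.868 and 0.334). With an estimated correlation none of these calls stayed (adjusted p 0.677 for meningeal, 0.677 for ependymal and 0.696 for choroid plexus markers in males, and 0.637 for meningeal markers in females). With camera on the authors' statistics, chosen after the data were seen, the ependymal list also passed in females, toward low extinction (adjusted p = 0.0489, median 0.23). The ependymal list rose and fell as a unit over male libraries with group means taken out (mean pairwise r 0.586, against 0.176 at the 95th percentile of 10000 matched random lists), as did the meningeal list over female libraries (0.397 against 0.168). Different amounts of ventricular lining or meninges in the dissected tissue may therefore account for the pattern, and a change of these cells in the mice would look alike. A single carry-over that includes choroid plexus stays open: over 12 libraries with group means taken out, choroid plexus and ependymal list means had a Pearson r of 0.5232 (exact permutation p = 0.157), a Spearman rho of 0.678 (exact permutation p = 0.0602) and an r of 0.408 without the 2 farthest libraries, and a first bound that required equal folds was wrong because the choroid markers moved as a unit between mice (estimated correlation 0.963 in males). A scaling factor from ribosomal RNA is argued against as the whole cause by size alone. The meningeal list mean differed between the sexes by -1.29, and by -1.18 over the median gene of each library, while the median gene differed by -0.11. The exact permutation p of the -1.18 was 0.005, the smallest 400 assignments can give. It adds no support, since the list was picked for its difference between the sexes and had the same p before.

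Tia1 and nuclear-retained transcripts were higher at low extinction in both sexes, though the list did not pass with an estimated correlation (adjusted p = 0.677 in males and 0.642 in females). In males the list means of the libraries overlapped between the groups, and replicate 1 of high extinction lay lowest. A trend of GC content and length is argued against as the whole cause, since most of the difference stayed after its removal. The mean of Tia1 and the 15 list members over the median gene of each library differed by 0.15 before (exact permutation p = 0.005) and 0.1337 after it (exact permutation p = 0.01). The removal moved the other genes by a median of 0.0241. Tia1 and the list were pooled after both were seen to be higher at low extinction, so these p-values do not support the difference itself. Alone, Tia1 had an exact permutation p of 0.065 and the list of 0.015 (adjusted p = 0.3075 over the lists). A larger share of nuclear or incompletely spliced RNA stays open. The 423 other lincRNA genes had a median of 0.10 in males and 0.08 in females, at the 100 and 99.8 percentile of matched random lists. The 95th percentile of those lists lay at 0.023 in males and 0.062 in females, so the female median of 0.076 was little above it. Such lists take genes as independent, so these percentiles do not measure the spread between mice. Tia1 also moved with the nuclear-retained list over 12 libraries with group means taken out (Pearson r = 0.7007, exact permutation p = 0.0417, and r = 0.652 without the 2 farthest libraries). Spearman rho was 0.615 (exact permutation p = 0.0818). Both were taken on TPM not set over the median gene, so a factor shared by all genes of a library moves Tia1 and the list together. Replicate 1 of the high-extinction males, with 23.5% of TPM from ribosomal RNA, had the lowest Tia1 (51.8 TPM). It also had the lowest means of the nuclear-retained, mitochondrially encoded and ribosomal protein lists. The correlation does not tell nuclear RNA from such a factor. A biological difference between extinction levels stays open beside a larger nuclear share.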

How the results depend on the processing

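Camera on the authors' statistics, the exact list test, the combined fold changes and the removal of ribosomal RNA-derived genes were chosen after the data were seen. No paired analysis was possible because replicate numbers follow the order of the records and link no mice. Where not stated, the cause was not tested. Of 113 named genes and lists, 62 kept direction and side of the threshold in all settings run. Apart from Zfp605 for the interaction, these were genes that did not pass in the first place. Every list that passed lost its call in at least 1 setting, as did Fam103a1 (1 setting) and Bzw1 (3 settings). Among the named genes and lists a call was lost in 145 and gained in 13 settings. The oligodendrocyte list on average reversed without replicate 2 of the high-extinction males (signed log10 camera p of 0.358, where the other libraries gave down to -4.77). Lists in males (9), females (10), on average (9) and for the interaction (12) became 0, 0, 0 and 0 with an estimated correlation, and 0, 0, 0 and 2 with fry. The estimated setting rests the test on few libraries, so these losses do not show that correlation between genes made the calls. Thalamus and habenula markers had an estimated correlation of -0.0020 in females and -0.0065 for the interaction, below the preset 0.01. Their camera adjusted p still rose from 0.000537 to 0.503 and from 0.000957 to 0.154. With the exact permutation of list means, the average and the interaction had 0 and 0. Even the smallest p that test can give, 0.005 for the meningeal and perineuronal net lists, had an adjusted p of 0.1025. These counts of 0 therefore decide little. With camera on the authors' statistics, males had 18, females 23, the average 13 and the interaction 20. Gene counts in males (0) became 2 without ribosomal RNA-derived genes and 1 in the joint fit; in females (2), 1 without a filter, 4 at a mean of at least 5 TPM, 4 with robust limma and 0 in the joint fit; for the interaction (1), 2 without a filter and 2 without trend. The authors' combined fold changes gave 194 genes on average and 60 for the interaction. The authors' calls in males rose from 101 to 173 at an adjusted p under 0.1, a looser threshold by construction. The correlation of male and female changes (0.02) was -0.0078 in the authors' tables.

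Leaving out each replicate in turn gave 2 to 6 genes in males (6 without replicate 1 of the high-extinction males), 4 to 10 in females (10 without replicate 2 of the high-extinction females), 0 to 3 on average and 1 to 4 for the interaction. It gave 9 to 12 lists in males, 8 to 14 in females, 7 to 10 on average and 8 to 15 for the interaction. The correlation ran from -0.0259, without replicate 2 of the high-extinction females, to 0.0908, and was -0.0118 without replicate 3 of the low-extinction females. Tia1 ran from 0.19 to 0.60 in males, 0.15 to 0.43 in females and 0.24 to 0.45 on average, where it passed at 0.45, 0.42 and 0.40 without replicate 3 of the high-extinction males, replicate 1 of the low-extinction males and replicate 1 of the low-extinction females. Depth per library is unknown, so its effect on low genes was not measured.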

Other observations

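The combined fold changes and the chromosome 7 window were chosen after the data were seen. Clock genes were among those called in males: in the authors' deposited table Nr1d1, a repressor of the circadian clock, was 1.26-fold and Nfil3 1.47-fold higher at high extinction, and Per3 was 1.21-fold higher at low extinction. The circadian list did not pass in males (20 genes, camera adjusted p = 0.160). In the authors' combined fold changes Nr1d1 had an adjusted p of 0.00044, Nfil3 of 0.00136 and Per3 of 0.0149. With camera on the combined values, also chosen after the data were seen, the circadian list passed toward high extinction (adjusted p = 0.0118). On log2(TPM + 1) it did not pass on average (camera adjusted p = 0.152). Tial1, the paralog of Tia1, was 1.16-fold higher at low extinction in females and 1.09-fold in males in the authors' deposited tables (DESeq2 adjusted p = 0.0422 and 0.717).

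Of the 109 genes higher at low extinction in the combined fold changes, 33 were non-coding, against 1 of the 85 genes higher at high extinction. Non-coding here means any gene not annotated as protein-coding. Against all other tested genes the share was 30.3% to 24.6%. That background was not matched on expression, and only 1.18% of the genes higher at high extinction were non-coding. It therefore does not decide whether non-coding genes were in excess, and neither contrast was tested over mice. Fos lay at 32.7 ± 2.47 and 40.1 ± 5.12 TPM in females against 10.2 ± 2.93 and 16.1 ± 7.58 TPM in males, at low and high extinction (SD, n = 3 each), levels from separately made tables that were not tested.

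Transcripts around Ube3a and Snhg14, an imprinted locus on chromosome 7, drew attention through 6 called genes. In a window drawn around them, 27 of 32 tested genes had a positive combined change, and 29 of the 32 were non-coding. No test of the window is given, since it was picked for its called genes and its genes overlap or lie beside them, and a local rise was not separated from a rise of non-coding or nuclear RNA. Ube3a itself had a combined log2 change of 0.09217 (95% interval 0.01 to 0.18, adjusted p = 0.446). Ube3a overlaps an antisense transcript, and whether the counts separated them is not given in the sources used here.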
